A study of Arabidopsis thaliana with 18 samples.

How the data were processed

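The series measured 22-nt small RNAs in Arabidopsis thaliana seedlings of 3 genotypes grown on MS medium or on MS medium with 1 µM of the hormone abscisic acid (ABA). The 18 libraries fell into 6 groups of 3 biological replicates, per the labels. The genotypes were the wild type Col-0, the mutant dcl4-2, which lacks the Dicer-like enzyme DCL4, and dcl4-2 dcl2-1, which lacks DCL4 and DCL2. The sample labels name whole seedlings 14 days old, while the growth field of the same labels speaks of aerial parts of older, soil-grown plants with no treatment. The genotype, medium and age given for each sample were followed here, and the growth field was left aside. Libraries were made with a small RNA kit and sequenced as paired-end reads of 150 bases, of which the first read was used, per the labels.

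Bowtie 1.2.2, SAMtools 1.9, DESeq2 and the genome build TAIR10 are named in the submitters' processing notes, without roles or order. The adapter trimming, the number of mismatches allowed and the treatment of reads that map to several places, such as those shared by MIR166 loci, by PPR genes or by NIA1 and NIA2, are not given in the sources used here. The deposited table has 32420 genes in lines, with 1 value per gene and group. These values are headed TPM per the file headers, but they were found to be reads scaled to library size (RPM): the values of a group were sums of exactly 3 fixed steps that were the same for every gene, so no gene length entered. The deposited RPM values are thus means over the 3 libraries of a group. The library total used for this scaling is not given in the sources used here. The same table gives log2 fold changes made by the authors for 4 comparisons, each with a p-value and an adjusted p-value from the authors. It gives no standard errors, and its adjusted p-value is empty for genes that were filtered out.

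Since each library adds whole multiples of its own step to a group mean, the reads of each library were recovered by solving for the 3 whole numbers that give the deposited mean. A single solution was found for each of the 32420 genes in 4 groups. In dcl4-2 dcl2-1 on MS, 32385 genes had 1 solution and 35 had several, of which the most even was used, so that their SD is the smallest possible. In dcl4-2 on ABA, 32418 genes were solved, and NIA1 and NIA2 were not searched because their counts were too high to be resolved. For these genes in that group the authors' mean and the authors' test are given, with no error. On simulated counts with the same steps, the true reads were among the solutions for 100% of genes in each group. As a further check, 1027 patterns of recovered reads were shared by at least 2 genes, and 0 of them had deposited fold changes that differed by more than 1e-06. The recovered libraries carry no replicate number. They are called A, B and C within a group by falling depth, which ties no library of one group to a library of another. Each pair of libraries of a group differed by more than counting noise (chi-square per gene between 1.54 and 30.6), so none is a copy, while repeat preparations of 1 sample are not excluded.

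The depth was uneven. The total behind the RPM values was 0.978, 0.869 and 0.581 M reads (M, mega) in Col-0 on MS, 0.831, 0.665 and 0.514 M in dcl4-2 on MS, and 1.10, 0.991 and 0.0953 M in dcl4-2 dcl2-1 on MS. On ABA it was 2.19, 1.83 and 1.53 M in Col-0, 12.7, 10.0 and 0.517 M in dcl4-2, and 1.28, 1.10 and 0.181 M in dcl4-2 dcl2-1. One read was worth between 0.0789 RPM, in dcl4-2 ABA library A, and 10.5 RPM, in dcl4-2 dcl2-1 MS library C.

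The comparisons were tested with limma 3.58.1 in R 4.3.3 on log2(RPM + 1), with a trend in the prior variance, 1 mean per group and all 18 libraries sharing the estimate of the spread. Genes entered with at least 1 RPM in at least 3 libraries, which left 5697 of the 21459 genes with any read, or 5695 where dcl4-2 on ABA enters. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the genes tested, and a gene passed at an adjusted p under 0.05. "Higher" and "lower" counts are of genes that passed. Fold changes are on the log2(RPM + 1) scale, which understates the change of genes with few reads. Replicates are biological per the labels, and p-values rest on a spread partly shared over groups and genes, not on the compared samples alone. The design, fixed before the data were examined, assumed TPM, and the test was kept for RPM, since it suits either unit. The comparisons, lists, named-gene rule and most alternatives were fixed then too.

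Named genes were chosen per comparison as the 10 largest fold changes in each direction among genes that passed and whose 3 libraries of one group all lay above the 3 of the other. NIA1, NIA2, SMXL4, SMXL5, DCL2, DCL4, AGO1, the TAS loci, MIR173 and MIR168A were added wherever they bear on the text. Of each other list the 2 members with the smallest p past the threshold and the 2 most abundant that did not pass could be named. For each difference between ABA effects the 5 smallest p in each direction were taken. Genes named outside this rule are marked as chosen after their values were seen.

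The 14 lists fixed in advance were TAS loci, MIRNA loci, pentatricopeptide repeat (PPR) genes targeted by TAS1, TAS2, miR161 or miR400, other targets of miRNAs and tasiRNAs, nitrate reductases, the SMXL family, silencing machinery, ABA-responsive genes, nitrogen uptake and assimilation, nuclear photosynthesis genes, chloroplast-encoded genes, mitochondrion-encoded genes, seed storage genes and root genes. TAS loci were not analysed here. The 10 lists with at least 3 tested members were tested with camera in limma at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 90 tests. Camera sets a list against the other tested genes, so up can mean a smaller fall. It was also run with an estimated correlation, and fry, which tests the list alone, beside it. Summed levels were compared by two-sided exact permutation tests, whose smallest possible p with 3 libraries against 3 is 0.1. Gene names and biotypes came from a reference table of the TAIR10.1 assembly, in which 31722 of the 32420 identifiers were found.

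Alternatives covered pseudocounts of 0.1 and 5, no filter, a filter of at least 5 RPM in 3 libraries, and rescaling by median-of-ratios factors from the 76 genes with reads in all libraries. Others were rescaling to an equal summed level of MIRNA loci, use of the compared groups alone, a minimum absolute log2 fold change of 1, array weights, and leaving out each library in turn. Chosen after seeing the data were voom weights on recovered reads, the most unequal solution for genes with several, leaving out the 2 libraries under 0.2 M reads, thinning dcl4-2 ABA libraries A and B to 0.665 M reads, the authors' own calls, and totals without NIA1 and NIA2. The count tests of edgeR and DESeq2 on recovered reads and the fits with a replicate block, though listed in advance, were not run here.

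The limma step was tested on simulated data with 200 of 5697 genes changed, each of at least 5 RPM, an assumed dispersion of 0.2 and the real depths. Over the 9 comparisons, between 9% and 37% of 4-fold changes and between 55% and 83% of 8-fold changes were recovered, with between 0 and 12 of 5497 unchanged genes called. These shares hold for that dispersion alone. Reads were handled in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.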

Results

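Small RNAs of 22 nt were profiled per gene in whole Arabidopsis seedlings of the mutants dcl4-2 and dcl4-2 dcl2-1 and of the wild type Col-0, each grown for 14 days on MS medium or on 1 µM ABA, a stress hormone. Each of the 6 groups had 3 biological replicates. The comparisons ask how 22-nt RNAs respond to ABA in each genotype, how loss of DCL4 changes them, and which of those changes depend on DCL2. The libraries held between 0.0953 M reads (M, mega), in dcl4-2 dcl2-1 MS library C, and 12.7 M reads, in dcl4-2 ABA library A. The knocked-out genes could not serve as a check of the labels, since DCL2 and DCL4 gave almost no 22-nt reads in any group. The highest group means were 0.364 RPM for DCL2, in Col-0 on ABA, and 0.145 RPM for DCL4, in dcl4-2 on ABA.

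The nitrate reductase genes NIA1 and NIA2, which encode the first enzyme of nitrate assimilation, gave the highest levels of all genes in dcl4-2 on both media, though not in the other groups. On MS, NIA1 stood at 508 ± 356 RPM in Col-0, 7435 ± 3382 RPM in dcl4-2 and 138 ± 42.4 RPM in dcl4-2 dcl2-1 (SD, n = 3 each). NIA2 stood at 397 ± 313, 4013 ± 1810 and 99.3 ± 53.9 RPM in the same groups. In dcl4-2 dcl2-1 on MS, 35 genes, among them NIA1, NIA2, MIR156a, MIR399a, MIR159b, MIR403, AT1G54410, AT3G06435 and MIR166e to MIR166g, had several solutions for their library values, of which the most even was used. Their SD there is the smallest possible, and the most unequal solution gave an SD of 149 RPM for NIA1, 130 for NIA2 and 236 for MIR156a. On ABA, NIA1 was at 68.4 ± 21.7 RPM in Col-0 and 513 ± 97.0 RPM in dcl4-2 dcl2-1, and NIA2 at 49.3 ± 10.7 and 351 ± 72.2 RPM (SD, n = 3 each). In dcl4-2 on ABA, the authors' deposited table gave means of 152172 RPM for NIA1 and 107247 RPM for NIA2, whose spread between libraries could not be recovered. These 2 genes made up 5.01% of all 22-nt RPM in genes in Col-0 on MS, 44.1% in dcl4-2 on MS, 89.2% in dcl4-2 on ABA and 1.92% in dcl4-2 dcl2-1 on MS. Their share was 0.460% in Col-0 on ABA and 5.32% in dcl4-2 dcl2-1 on ABA.

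**Figure D1:**
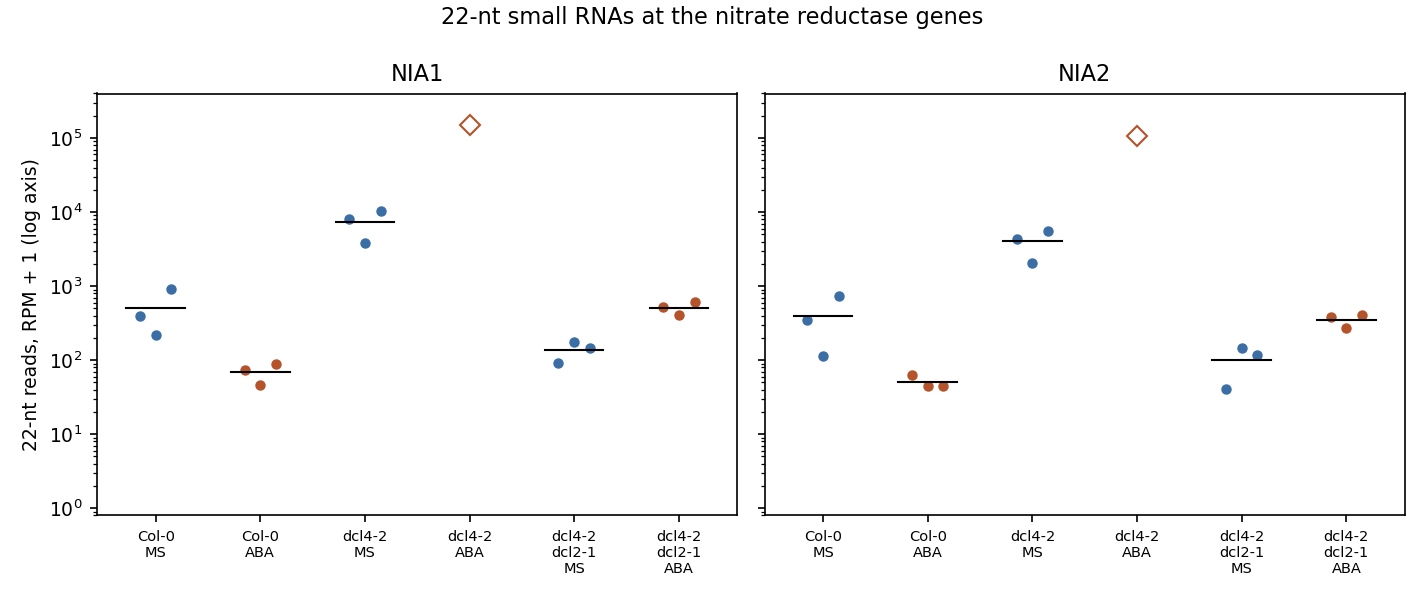
22-nt reads at NIA1 and NIA2 in RPM + 1 on a log axis, by genotype and medium; points are libraries, lines are group means, the open diamonds are the authors' means for dcl4-2 on ABA, whose libraries were not resolved, and those of dcl4-2 dcl2-1 on MS are the most even solution. The NIA1 mean in dcl4-2 on ABA was 152172 RPM.

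The summed 22-nt level over genes was 18085 ± 2050 RPM in Col-0 on MS, 25977 ± 6503 in dcl4-2 and 12367 ± 1101 in dcl4-2 dcl2-1 (SD, n = 3 each). On ABA it was 25621 ± 5149 RPM in Col-0, 290702 RPM in dcl4-2, with no error, and 16228 ± 1569 RPM in dcl4-2 dcl2-1. The ABA to MS ratio was 1.42 in Col-0, or 0.591 with summed MIRNA levels made equal, 11.2 in dcl4-2 and 1.31 in dcl4-2 dcl2-1. Without NIA1 and NIA2 these ratios were 1.48, 2.15 and 1.27, each with an exact permutation p of 0.1. The ratio of dcl4-2 to Col-0 was 1.44 on MS and 0.846 without the nitrate reductases, exact permutation p = 0.2 for both. On ABA it was 11.3, and 1.23 without them, exact permutation p = 0.3. The ratio of dcl4-2 dcl2-1 to dcl4-2 was 0.476 on MS and 0.0558 on ABA, and 0.835 and 0.491 without the nitrate reductases. Against Col-0 it was 0.684 on MS and 0.633 on ABA. Each ratio of dcl4-2 dcl2-1 had an exact permutation p of 0.1, except 0.0558 (untested). Scaling kept the 259419 RPM of NIA1 and NIA2 in dcl4-2 on ABA, so 1.23 and 2.15 may be too low and 0.491 too high.

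**Figure D2:**
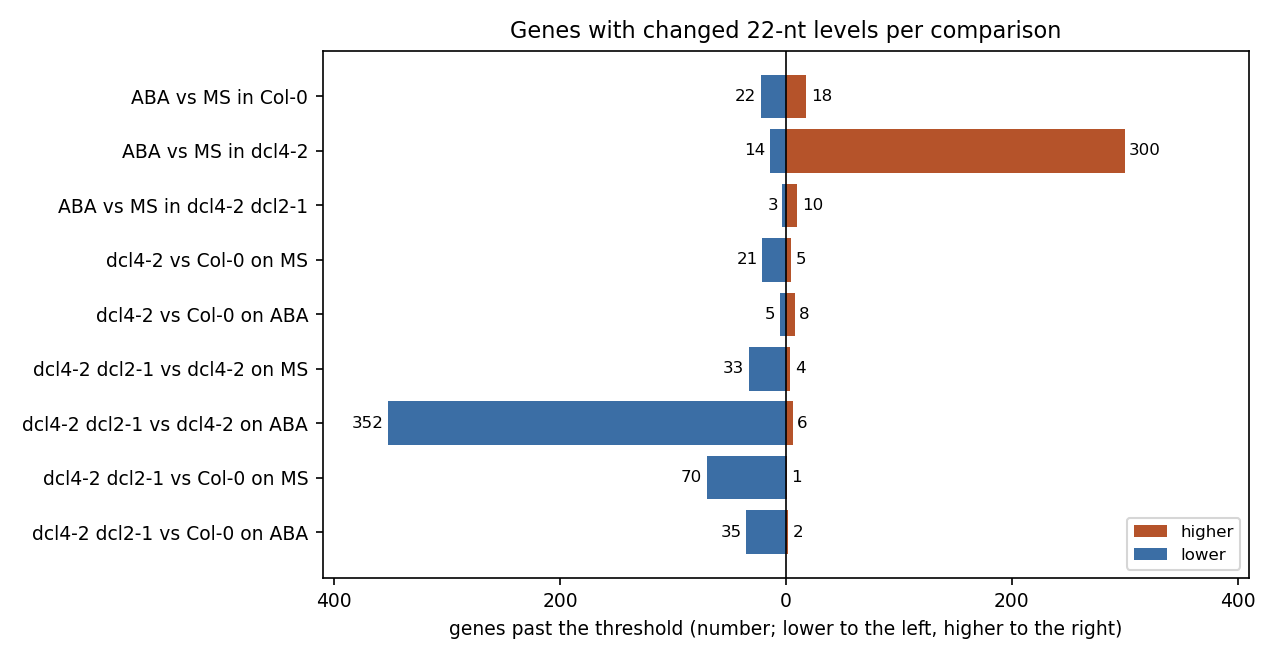
Number of genes that passed an adjusted p under 0.05 in limma in each of the 9 comparisons, with genes lower in the first-named group to the left of 0 and genes higher to the right. ABA raised 300 genes in dcl4-2, and 352 genes were lower in dcl4-2 dcl2-1 than in dcl4-2 on ABA.

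In Col-0, ABA lowered 22-nt RNAs at REV, PHB, HB-8, PHV, SMXL4, GLT1 and both nitrate reductases, and raised them at MIR319c, MIR319a, MIR159b and MIR400. REV, a class III HD-ZIP gene, fell from 97.9 ± 80.7 RPM to 0.334 ± 0.293 RPM (SD, n = 3 each), a log2 fold change of -5.69 ± 0.76 (SE, limma adjusted p = 4.62e-08). Its relatives PHB, HB-8 and PHV stood at 65.9 ± 46.2, 41.8 ± 31.9 and 22.9 ± 16.9 RPM on MS and had no reads in any of the 3 ABA libraries, with limma adjusted p of 4.62e-08, 1.36e-08 and 1.12e-05. SMXL4, which acts in phloem formation, fell from 54.3 ± 29.6 to 0.152 ± 0.264 RPM, a log2 fold change of -5.45 ± 0.79 (SE, limma adjusted p = 3.66e-07). GLT1, the NADH-dependent glutamate synthase, fell from 62.2 ± 43.6 to 1.54 ± 0.933 RPM, a log2 fold change of -4.43 ± 0.80 (SE, limma adjusted p = 1.32e-04). NIA1 fell by 2.69 ± 0.37 and NIA2 by 2.63 ± 0.44 on the log2 scale, with limma adjusted p of 9.54e-08 and 2.23e-05. Lower as well were BAM3, a receptor kinase of the phloem, at 0.957 against 40.6 ± 31.9 RPM, the clock regulator TIC at 0.546 against 33.5 ± 34.5 RPM, GUN5, a subunit of magnesium chelatase, at 3.40 against 60.7 ± 48.5 RPM, and the dehydrin gene AT1G54410 at 2.59 against 39.1 ± 27.3 RPM. MIR319c rose from 350 ± 171 to 2750 ± 1501 RPM, a log2 fold change of 2.97 ± 0.41 (SE, limma adjusted p = 7.89e-08). AT3G06435 rose from 233 ± 119 to 1441 ± 94.2 RPM, a log2 fold change of 2.78 ± 0.38 (SE, limma adjusted p = 7.89e-08). Higher as well were MIR319a at 189 ± 110 against 17.2 ± 5.81 RPM, MIR159b at 452 ± 248 against 78.1 ± 26.4 RPM, MIR400 at 30.6 ± 16.1 against 2.41 RPM, and MS2, a methionine synthase gene, at 38.2 ± 38.5 against 1.45 RPM. The chloroplast features ATCG00870 and ATCG01270, whose reads were identical, rose together from 26.2 ± 13.3 to 164 ± 29.5 RPM. For each of these genes the libraries of the media did not overlap.

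By limma, 18 genes were higher and 22 lower on ABA in Col-0, and 908 had an unadjusted p under 0.05. With the compared groups alone 0 genes passed, with 926 at an unadjusted p under 0.05. The libraries did not overlap in 18 of the higher and 19 of the lower genes. The median log2 fold change of all tested genes was 0.26, and making the summed MIRNA level equal shifted it by -0.37 and gave 2 higher and 25 lower genes. Leaving out Col-0 MS library C gave 2 higher and 8 lower genes, and NIA2, BAM3, TIC, GUN5, AT1G54410, MS2, MIR319a, MIR400, MIR159b and ATCG00870 lost their calls (limma adjusted p from 0.0558 for NIA2 to 0.243 for GUN5). Leaving out Col-0 ABA library C gave 4 and 12, and MIR319a, MIR400, MIR159b, GUN5, TIC, AT1G54410 and ATCG00870 lost theirs (0.0871 to 0.248). Leaving out Col-0 ABA library A gave 4 and 11, without the calls of MS2, MIR319a, MIR400, AT1G54410, TIC, GUN5 and ATCG00870 (0.0529 to 0.180), and library B 10 and 13, without those of MIR400, BAM3, GUN5 and ATCG00870 (0.0804 to 0.113). Without Col-0 MS library A, BAM3, TIC, GUN5, MIR400 and ATCG00870 did not pass (0.084 to 0.108). The authors' deposited table called 32 genes higher and 20 lower in this comparison, of which limma called 10 and 15 in the same direction.

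Of 5 tested SMXL members, SMXL3, SMXL4 and SMXL5 fell in Col-0, over all genes and adjusted over the list alone, and their sum went from 148 ± 100 to 4.60 ± 4.06 RPM. Camera, which sets a list against the other tested genes, called the family down (adjusted p = 2.65e-07, and 0.0191 with an estimated correlation). SMXL5 was at 2.50 ± 3.78 against 84.0 ± 67.8 RPM with overlapping libraries, and its limma adjusted p of 0.00111 became 0.0699 to 0.0984 without Col-0 MS library A or C or ABA library B. SMXL7 and SMAX1 stayed under 1 RPM in both groups. Of 50 listed MIRNA loci tested, MIR319c, MIR319a, MIR159b and, named after its values were seen, MIR403 rose and 0 fell, while 7 rose adjusted over the list alone. Camera called them up (adjusted p = 1.38e-04, and 0.396 with an estimated correlation). MIR168a stood at 103 ± 56.0 against 17.5 ± 8.51 RPM without passing (limma adjusted p = 0.0742, and 4.92e-04 in the authors' test). None of 17 PPR targets passed over all genes, with 12 at an unadjusted p under 0.05, and 8 rose adjusted over the list alone, with a camera call up (adjusted p = 2.65e-07, and 0.0769 with an estimated correlation). Their sum was 594 ± 311 RPM on ABA and 111 ± 33.8 RPM on MS. In the list of other miRNA and tasiRNA targets, which holds neither the class III HD-ZIP genes nor ARF6 or ARF10, AGO2 fell from 17.6 ± 13.2 to 0.669 RPM (limma adjusted p = 0.00971), a call that ended without Col-0 MS library A or C or Col-0 ABA library A or C (0.0583 to 0.204). AGO2 was also the 1 member of the silencing machinery that passed. Of 8 tested genes of nitrogen uptake and assimilation, GLT1 alone passed and camera called the list down (adjusted p = 0.00324, and 0.114 with an estimated correlation). None of 25 nuclear photosynthesis genes passed, with 2 at an unadjusted p under 0.05 and a camera call down (adjusted p = 5.21e-05, and 0.270 with an estimated correlation). Of 83 chloroplast-encoded genes ATCG00870 and ATCG01270 rose, and camera called no direction (adjusted p = 0.121), while the MIRNA rescaling gave a call down (1.42e-04).

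In dcl4-2, ABA raised 22-nt RNAs at 300 genes, 210 annotated as pseudogenes. The MYB gene AT2G03500 went from no reads in any of the 3 MS libraries to 35.1 ± 15.1 RPM (SD, n = 3; limma adjusted p = 6.23e-10). BGLU29, a beta-glucosidase gene, went likewise from no reads to 17.9 ± 5.43 RPM (limma adjusted p = 6.16e-07). MIR319c rose from 78.4 ± 51.5 to 1761 ± 597 RPM, a log2 fold change of 4.62 ± 0.41 (SE, limma adjusted p = 5.09e-16). MIR403 rose from 38.2 ± 9.18 to 589 ± 54.4 RPM, a log2 fold change of 3.94 ± 0.49 (SE, limma adjusted p = 2.28e-09). MIR173, whose product starts tasiRNA formation at TAS1 and TAS2, rose from 0.649 ± 1.12 to 29.3 ± 5.28 RPM, a log2 fold change of 4.39 ± 0.80 (SE, limma adjusted p = 2.53e-04). MIR163 was at 21.1 ± 8.79 against 0.649 RPM and the disease resistance gene AT5G43740 at 43.2 ± 16.8 against 3.06 ± 3.74 RPM. ADC2, an arginine decarboxylase gene, was at 125 ± 172 against 4.35 ± 2.73 RPM. The dehydrin gene AT1G54410 fell from 39.9 ± 10.2 to 1.05 ± 0.934 RPM, a log2 fold change of -4.42 ± 0.80 (SE, limma adjusted p = 2.53e-04). Lower as well were MIR850 at 3.94 ± 1.73 against 42.7 ± 27.9 RPM, AT4G27090 at 0.424 against 7.91 ± 0.467 RPM, and ASN1, an asparagine synthetase gene, at 0.0263 against 5.76 ± 4.37 RPM. For each of these genes the libraries of the media did not overlap. In the authors' deposited table NIA1 rose by 4.36 and NIA2 by 4.74 on the log2 scale, with adjusted p of 5.26e-11 and 1.76e-10 from the authors' test. SMXL4 stood at 82.5 ± 56.5 against 18 ± 1.46 RPM and SMXL5 at 20.9 ± 11.7 against 10.5 ± 6.55 RPM, and neither passed (limma adjusted p = 0.122 and 0.546). AGO1 at 3.50 ± 1.35 against 2.21 ± 1.93 RPM and MIR168a at 76.8 ± 20.9 against 23.2 ± 12.1 RPM did not pass either (limma adjusted p = 0.506 and 0.0962). The authors' test did pass SMXL4 and MIR168a (adjusted p = 0.00947 and 0.0326).

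By limma, 300 genes were higher and 14 lower on ABA in dcl4-2, and 1419 had an unadjusted p under 0.05. With the compared groups alone 6 were higher and 1 lower. The libraries did not overlap in 298 higher and 14 lower genes. The all-gene median log2 fold change was 0.51, and the MIRNA rescaling shifted it by -0.48 and left 6 higher and 18 lower genes, among which the direction of the imbalance turned. Voom weights gave 112 higher and 148 lower, and the authors' deposited table gave 101 higher and 31 lower, of which limma shared 75 and 7. Leaving out dcl4-2 ABA library C left 15 higher and 1 lower, leaving out library A 73 and 1, and leaving out dcl4-2 MS libraries A, B and C 157 and 17, 84 and 7, and 91 and 20. MIR163, AT5G43740, MIR850, AT4G27090 and ASN1 lost their calls without dcl4-2 ABA library C (limma adjusted p from 0.0533 to 0.163), and MIR850, AT4G27090 and ASN1 without library A (0.0534 to 0.0891). ADC2 and ASN1 lost theirs without library B (0.0758 and 0.0756), MIR850 without dcl4-2 MS library C (0.0681), and ASN1 without dcl4-2 MS library A or B (0.0753 and 0.148).

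Among the 50 listed MIRNA loci, 15 rose and 0 fell in dcl4-2, and 25 rose adjusted over the list alone, while their sum went from 3447 to 10314 RPM. Camera called them up (adjusted p = 1.36e-10, and 0.125 with an estimated correlation). The abundant MIR162b stood at 373 ± 28.2 against 478 ± 121 RPM and did not pass (limma adjusted p = 0.575). Of 17 PPR targets AT1G62860 and AT1G12300 and, named after their values were seen, AT1G63150 and AT1G63400 rose, and 9 adjusted over the list alone, with a camera call up (adjusted p = 0.0113, and 0.396 with an estimated correlation). AT1G62860 was at 6.01 ± 3.39 against 0.802 RPM and AT1G12300 at 2.43 ± 0.532 RPM against no reads. AT1G62860 lost its call without dcl4-2 ABA library A or C or dcl4-2 MS library B or C (limma adjusted p from 0.0828 to 0.185), and AT1G12300 without any 1 of the 6 libraries (0.0713 to 0.0993). Of 13 other miRNA and tasiRNA targets AT5G43740, AT5G43730 and, named after its values were seen, AT1G51480 rose, both adjustments alike, with a camera call up (adjusted p = 0.0353, 0.233 with an estimated correlation and 0.169 with the MIRNA rescaling). AT5G43730, a disease resistance gene, was at 19 ± 5.91 against 1.05 RPM, and its limma adjusted p of 0.00262 became 0.0533 without dcl4-2 ABA library C. None of the 5 SMXL members passed, with 1 at an unadjusted p under 0.05, and camera called no direction (adjusted p = 0.954). None of 25 nuclear photosynthesis genes passed over all genes, with 8 at an unadjusted p under 0.05, while 3 fell adjusted over the list alone and the sum was 86.1 ± 19.5 against 276 ± 99.3 RPM. Camera called them down (adjusted p = 2.01e-13, and 0.0445 with an estimated correlation). Of 83 chloroplast-encoded genes, ATCG00870 and ATCG01270 rose from 11.3 ± 5.71 to 85.5 ± 17.6 RPM, a call that ended without dcl4-2 ABA library C (limma adjusted p = 0.0705), while camera called the list down (adjusted p = 1.08e-04, and 0.314 with an estimated correlation). Of 67 mitochondrion-encoded genes ATMG00180 passed over all genes and none adjusted over the list alone, with 12 at an unadjusted p under 0.05, a call that ended without any 1 of the 6 libraries (limma adjusted p from 0.0586 to 0.222). In nitrogen uptake and assimilation ASN1 fell, and camera called no direction (adjusted p = 0.258), but down with the MIRNA rescaling (0.0279).

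In dcl4-2 dcl2-1, ABA raised a short set of MIRNA loci and both nitrate reductases and lowered 3 genes. MIR319c rose from 26.4 ± 15 to 1687 ± 1051 RPM (SD, n = 3 each), a log2 fold change of 5.93 ± 0.41 (SE, limma adjusted p = 6.38e-23). MIR403 rose from 50.8 ± 28.9 to 377 ± 92.9 RPM, a log2 fold change of 2.98 ± 0.49 (SE, limma adjusted p = 2.44e-05), and MIR400 from 1.01 ± 1.75 to 26.8 ± 9.73 RPM, a log2 fold change of 4.06 ± 0.78 (SE, limma adjusted p = 8.49e-04). ATCG00870 and ATCG01270 rose from 6.09 ± 3.98 to 175 ± 42.1 RPM, a log2 fold change of 4.75 ± 0.68 (SE, limma adjusted p = 6.02e-07). NIA1 rose by 1.92 ± 0.37 and NIA2 by 1.98 ± 0.44 on the log2 scale, with limma adjusted p of 8.55e-04 and 0.0104. MIR319a, MIR159b and MIR399a were higher as well, the last at 386 ± 225 against 112 ± 23.9 RPM. AT1G54410 fell from 73.7 ± 20.7 to 2.67 ± 2.50 RPM, a log2 fold change of -4.52 ± 0.80 (SE, limma adjusted p = 1.51e-04). MIR156a, a regulator of developmental phase change, fell from 237 ± 26.2 to 18.2 ± 14.2 RPM, a log2 fold change of -3.93 ± 0.67 (SE, limma adjusted p = 7.35e-05). AT1G49700 fell from 21.2 ± 18.9 to 1.08 ± 1.18 RPM. The libraries of the media did not overlap in any of these 13 genes, 10 higher and 3 lower, and 454 genes had an unadjusted p under 0.05. SMXL4 and SMXL5 stayed at 0.302 and 3.31 RPM on ABA and did not pass (limma adjusted p = 0.996 and 0.658).

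With the most unequal solution on MS, 5 of the 13 calls stayed, and MIR319a, MIR403, MIR159b, MIR399a, NIA1, NIA2, MIR156a and AT1G49700 lost theirs (limma adjusted p from 0.0950 to 0.789). With the compared groups alone 0 genes passed, with 148 at an unadjusted p under 0.05. In dcl4-2 dcl2-1 the NIA2 call ended without MS library A or ABA library A or C (limma adjusted p from 0.0688 to 0.202), that of MIR319a without MS library C or ABA library B or C (0.111 to 0.656), and that of MIR159b without ABA library B or C (0.0789 and 0.0917). MIR399a lost its call without MS library B or C or ABA library B or C (0.0505 to 0.414), and AT1G49700 without MS library A or C or ABA library B or C (0.0817 to 0.332). The count moved to 11 higher and 14 lower without MS library A, 15 and 22 without MS library B, and 14 and 8 without ABA library A. The authors' deposited table gave 4 genes as higher and 1 as lower, and limma called each of these 5 in the same direction. That table gave NIA1 and NIA2 log2 fold changes of 2.00 and 1.99 with an adjusted p of 0.955 for both.

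Of the listed MIRNA loci in dcl4-2 dcl2-1, MIR319c, MIR403, MIR159b and MIR319a rose and MIR156a fell, while 8 rose and 9 fell adjusted over the list alone, and camera called no direction (adjusted p = 0.429). None of the PPR targets passed (sum 1.82 ± 3.16 against 1.22 ± 2.11 RPM), nor of the SMXL members, silencing machinery or nitrogen uptake and assimilation genes, with 0 of each at an unadjusted p under 0.05 in limma, nor of the other miRNA and tasiRNA targets, with 1. None of the 25 nuclear photosynthesis genes passed, with 4 at an unadjusted p under 0.05, and camera called them down (adjusted p = 1.08e-04, and 0.28 with an estimated correlation). Chloroplast-encoded genes were called up (adjusted p = 0.0172, 0.514 with an estimated correlation and 0.0969 with the MIRNA rescaling), with 3 higher and 1 lower adjusted over the list alone.

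The ABA effect differed between dcl4-2 and Col-0 in 15 genes by limma's test of the difference, and 370 had an unadjusted p under 0.05. All 15 had the more positive log2 change in dcl4-2. NIA1 and NIA2, which fell in Col-0 and rose in dcl4-2, were not tested. The differences on the log2 scale were 7.32 ± 1.12 for SMXL4, 5.09 ± 0.85 for AT2G03500, 5.20 ± 0.90 for HB-8, 5.06 ± 0.95 for AT5G17980 and 5.53 ± 1.07 for PHB (SE; limma adjusted p = 1.36e-05, 9.95e-05, 1.37e-04, 8.51e-04 and 0.00128). All named had at most 1 read in some group, so size depends on the pseudocount. HB-8 and PHB differed through their fall in Col-0, as dcl4-2 had 0 and 8.16 RPM on MS and 0.119 and 5.72 on ABA. SMXL5 differed by 5.22 ± 1.22 (SE, limma adjusted p = 0.0177). The count fell to 5, 7, 7, 8, 7, 9 and 6 without Col-0 MS library A or C, dcl4-2 MS library B, Col-0 ABA library A, B or C, or dcl4-2 ABA library C in turn, and rose to 23 without Col-0 MS library B. It was 3 with the MIRNA rescaling. SMXL5 lost its call without Col-0 MS library A or C, dcl4-2 MS library B, Col-0 ABA library B or C, or any dcl4-2 ABA library (limma adjusted p from 0.0526 to 0.293).

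Between dcl4-2 dcl2-1 and dcl4-2, the ABA effect differed in 12 genes, 1 with the more positive log2 change in dcl4-2 dcl2-1 and 11 with the more negative, and 624 had an unadjusted p under 0.05. MIR399a differed by 2.68 ± 0.58, AT2G03500 by -5.09, MIR156a by -5.37 ± 0.95 and MIR166f, MIR166e and MIR166g by -2.76, -2.76 and -2.75 on the log2 scale (SE, limma adjusted p = 0.00727, 1.99e-04, 4.61e-04 and, for the last 3, 5.00e-04). The MIR166 loci had nearly identical levels, and reads they share could not be told apart. The MIRNA rescaling gave 3 genes with the more positive and 1 with the more negative change. MIR156a fell in dcl4-2 dcl2-1 from 237 to 18.2 RPM and went from 24.5 to 66.7 RPM in dcl4-2. With the most unequal solution on MS 3 genes, each more negative, were called, and MIR399a, MIR156a and the MIR166 loci lost their calls (limma adjusted p from 0.290 to 0.742). The count was 4 without dcl4-2 ABA library C, 19 without dcl4-2 dcl2-1 MS library C and 7 without dcl4-2 dcl2-1 ABA library C. Without dcl4-2 ABA library C the MIR166 loci lost their calls (limma adjusted p = 0.0555), and MIR399a lost its call without dcl4-2 MS library C or dcl4-2 dcl2-1 MS library B or ABA library C (0.0509 to 0.168).

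Under ABA, Col-0 and dcl4-2 shared 11 higher genes, Col-0 and dcl4-2 dcl2-1 shared 7, and the mutants 7. Independent lists would share 0.948, 0.0316 and 0.421 (Fisher's exact p = 1.66e-10, 9.87e-17 and 8.04e-09). AT1G54410 alone was lower in all 3 genotypes. These lists share no library but are not independent, as each gene's spread is shared and ATCG00870 and ATCG01270, with identical reads, count as 2. The p-values may be too small. Counting both directions, 12, 8 and 8 genes were shared, 3, 2 and 3 with MIRNA rescaling and 3, 1 and 5 with no filter. The compared groups alone gave 0 each. Without Col-0 MS library C the pairs with Col-0 shared 2 and 1, and without dcl4-2 ABA library C the last pair shared 4.

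**Figure D3:**
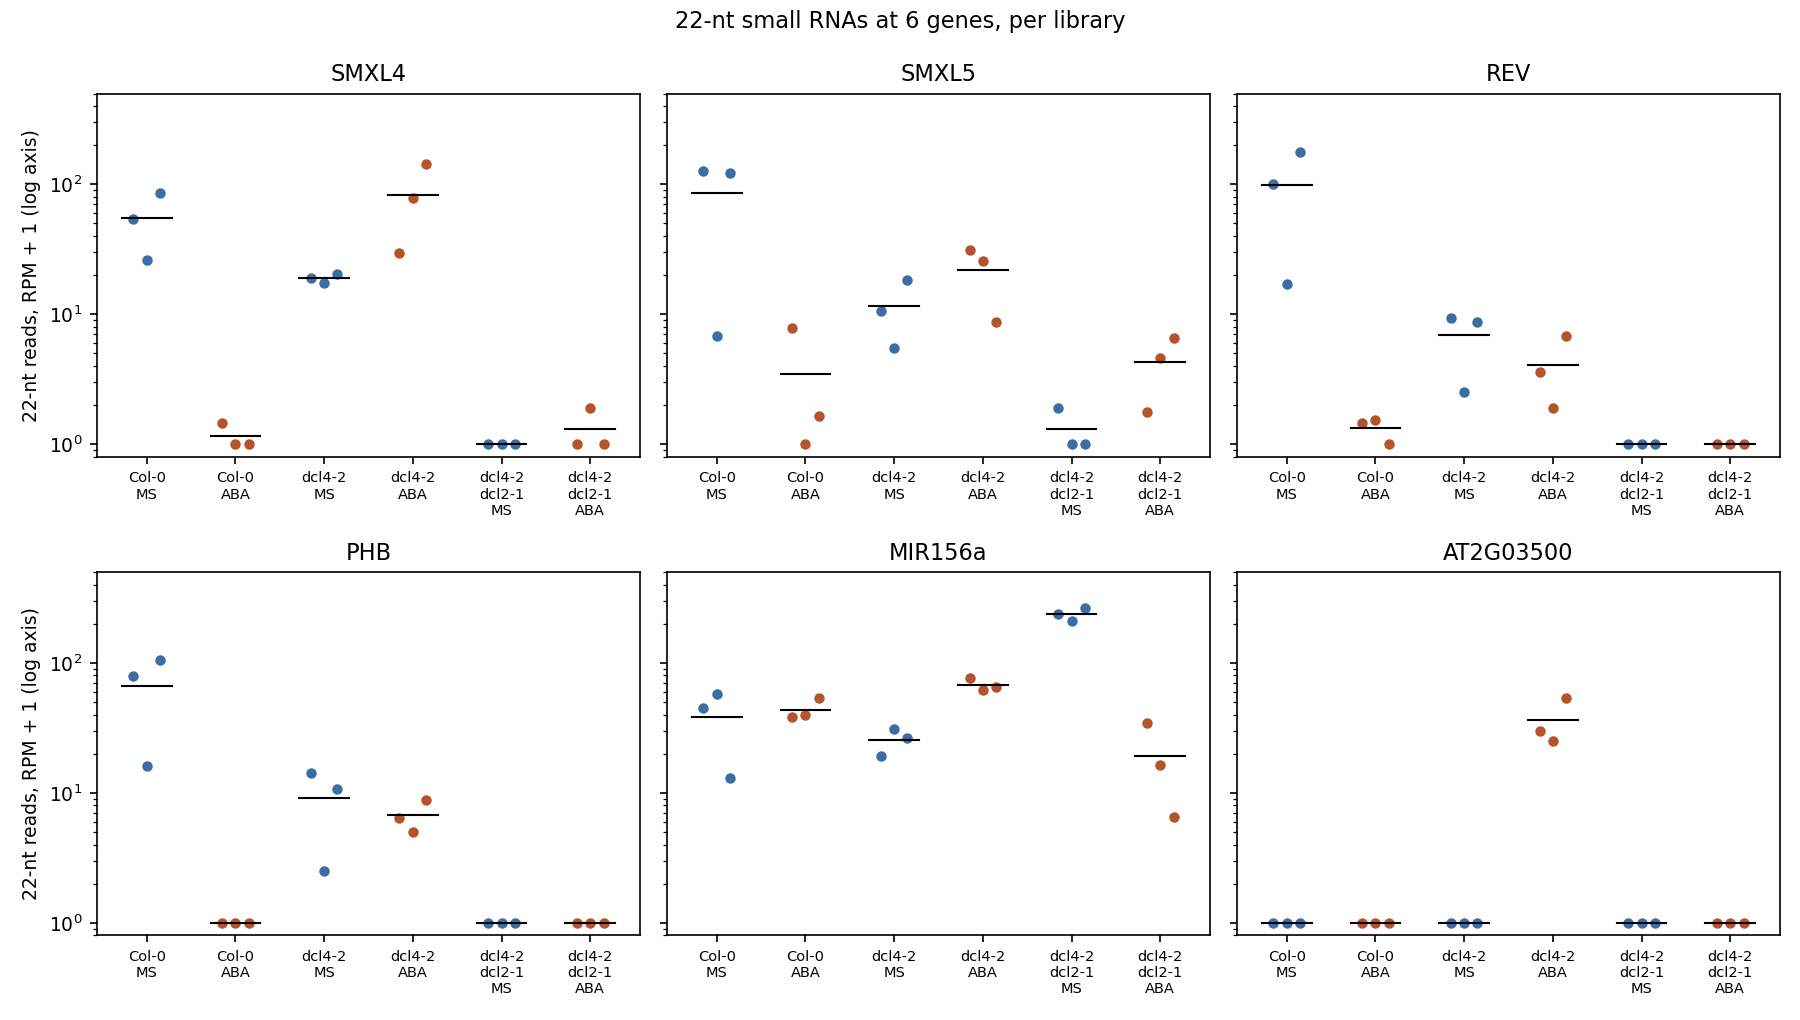
22-nt reads at SMXL4, SMXL5, REV, PHB, MIR156a and AT2G03500 in RPM + 1 on a log axis, by genotype and medium; points are libraries and lines are group means, and MIR156a in dcl4-2 dcl2-1 on MS is the most even solution. AT2G03500 had reads in dcl4-2 on ABA, at 35.1 RPM, and in no other group.

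On MS, loss of DCL4 raised 22-nt RNAs at the nitrate reductases and lowered them at HB-8, REV, ARF6 and the PPR genes AT1G63400 and AT1G63080. NIA1 was higher in dcl4-2 than in Col-0 by 3.99 ± 0.37 and NIA2 by 3.59 ± 0.44 on the log2 scale (SE, limma adjusted p = 1.42e-14 and 2.75e-09), with every dcl4-2 library above every Col-0 library. Both SE rest partly on the most even solution in dcl4-2 dcl2-1 on MS and may be too small. IBR10, FD1 and SAC9 were at 3.60 ± 1.08, 3.20 ± 1.76 and 3.05 ± 2.59 RPM, against no reads in Col-0. HB-8 and the PPR gene AT1G63400 had no reads in dcl4-2 and stood at 41.8 ± 31.9 and 22.2 ± 9.34 RPM in Col-0. AT1G63080, also a PPR gene, was at 0.649 ± 1.12 against 24.2 ± 13.0 RPM, a log2 fold change of -4.00 ± 0.81 (SE, limma adjusted p = 0.00208). ARF6, an auxin response factor gene, was at 0.501 against 30.1 ± 24.1 RPM, a log2 fold change of -3.79 ± 0.73 (SE, limma adjusted p = 9.13e-04). REV was at 5.90 ± 3.82 against 97.9 ± 80.7 RPM (limma adjusted p = 0.00682), and GUN5, PHV and ARF10 were lower as well. SMXL4, at 18 ± 1.46 against 54.3 ± 29.6 RPM, and SMXL5, at 10.5 ± 6.55 against 84.0 ± 67.8 RPM, did not pass (limma adjusted p = 0.598 and 0.384).

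By limma, 5 genes were higher and 21 lower in dcl4-2 than in Col-0 on MS, 524 had an unadjusted p under 0.05, and the libraries did not overlap in 5 and 18 of them. With the compared groups alone 0 genes passed, with 177 at an unadjusted p under 0.05. Leaving out Col-0 MS library C gave 2 higher and 6 lower genes, and Col-0 MS library A 2 and 13. Without either, ARF6, REV, PHV, ARF10, GUN5, FD1, IBR10 and SAC9 lost their calls (limma adjusted p from 0.0601 to 0.275 without C and 0.0552 to 0.134 without A). Leaving out dcl4-2 MS library B gave 3 and 8, without the calls of REV, PHV, ARF10, FD1, IBR10 and SAC9 (0.0788 to 0.181), and dcl4-2 MS library C 4 and 9, without those of GUN5, PHV, ARF10, FD1 and IBR10 (0.0615 to 0.344). PHV, ARF10 and GUN5 also lost theirs without dcl4-2 MS library A (0.0613 to 0.126), and FD1, IBR10 and SAC9 without Col-0 MS library B (0.0646 to 0.0797). Voom weights, fitted without NIA1 and NIA2, called 0 genes higher and 12 lower, and the MIRNA rescaling 8 and 38.

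Of 17 PPR targets AT1G63080 and AT1G63400 fell in dcl4-2 on MS, and 8 adjusted over the list alone, with sums of 10.2 ± 5.13 against 111 ± 33.8 RPM. Camera called them down (adjusted p = 2.12e-08, and 0.0639 with an estimated correlation). SMXL3 was the 1 SMXL member that fell over all genes, at 0.401 against 8.62 RPM with overlapping libraries, and 2 fell adjusted over the list alone. Camera called the family down (adjusted p = 0.0233, 0.267 with an estimated correlation and 0.0658 with the MIRNA rescaling). SMXL3 lost its limma call without Col-0 MS library A or C or dcl4-2 MS library B or C (adjusted p from 0.060 to 0.141). Among listed MIRNA loci MIR319c alone fell, both adjustments alike, at 78.4 ± 51.5 against 350 ± 171 RPM, and its limma adjusted p of 3.74e-04 became 0.060 without Col-0 MS library A. No other list had a member past limma's threshold over all genes apart from the nitrate reductases, where both rose, while 3 other miRNA and tasiRNA targets fell adjusted over the list alone.

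On ABA, SMXL4 was higher in dcl4-2 than in Col-0, at 82.5 ± 56.5 against 0.152 ± 0.264 RPM (SD, n = 3 each), a log2 fold change of 5.93 ± 0.79 (SE, limma adjusted p = 6.59e-08). AT2G03500 stood at 35.1 ± 15.1 RPM against no reads. NAC083, a transcription factor gene, was at 12.9 ± 6.29 against 0.152 RPM, a log2 fold change of 3.51 ± 0.65 (SE, limma adjusted p = 4.13e-04). ADC2 was at 125 ± 172 against 2.91 ± 0.305 RPM and BGLU29 at 17.9 ± 5.43 against 1.32 RPM. The other higher genes were ABCC3, AT4G09584 and AT3G16560. The PPR genes AT1G62914, AT1G63080 and AT1G63400 were lower in dcl4-2, at 2.41 ± 2.12, 3.33 ± 2.89 and 4.70 ± 0.958 RPM against 144 ± 85.9, 151 ± 87.4 and 146 ± 90.5 RPM. Their log2 fold changes were -5.56 ± 0.78, -5.38 ± 0.81 and -4.53 ± 0.77 (SE, limma adjusted p = 3.27e-07, 1.96e-06 and 4.86e-05). AT1G66490 and AT3G49520 were lower as well. The libraries did not overlap in these 8 higher and 5 lower genes, and 335 genes had an unadjusted p under 0.05 in limma. NIA1 and NIA2 were compared in this setting by their means alone, 152172 and 107247 RPM in the authors' deposited table for dcl4-2.

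The count on ABA was 3 higher and 3 lower without Col-0 ABA library A, 4 and 4 without Col-0 ABA library B and 4 and 3 without dcl4-2 ABA library B, and 2 and 3 with the MIRNA rescaling, which shifted the all-gene median of 0.08 by -0.14. Array weights gave 173 and 56. ADC2 lost its call without Col-0 ABA library A or B or dcl4-2 ABA library B (limma adjusted p from 0.0642 to 0.287), BGLU29 without Col-0 ABA library A (0.107), and AT1G66490 without Col-0 ABA library A or dcl4-2 ABA library B or C (0.0582 to 0.0879). ABCC3 lost it without any 1 of the 6 libraries (0.0575 to 0.242), AT3G16560 without any but dcl4-2 ABA library C (0.0976 to 0.320), and AT3G49520 and AT4G09584 without any but Col-0 ABA library C (0.0869 to 0.329 and 0.0919 to 0.542).

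Of 17 PPR targets AT1G62914, AT1G63080 and AT1G63400 fell on ABA, while 13 fell and 1 rose adjusted over the list alone, and camera called them down (adjusted p = 2.37e-20, and 0.00843 with an estimated correlation). Their sum was 62.3 ± 31.7 against 594 ± 311 RPM. Other miRNA and tasiRNA targets had 0 members past limma's threshold over all genes, 7 at an unadjusted p under 0.05 and 5 higher adjusted over the list alone, with a camera call up (adjusted p = 5.34e-06, and 0.0191 with an estimated correlation). SMXL4 was the 1 SMXL member that rose, with 2 adjusted over the list alone (camera adjusted p = 1.82e-04, and 0.0688 with an estimated correlation). None of the MIRNA loci passed, 13 had an unadjusted p under 0.05, 7 rose adjusted over the list alone, and camera called them up (adjusted p = 1.59e-04, and 0.396 with an estimated correlation). For nitrogen uptake and assimilation, 3 rose adjusted over the list alone and 0 over all genes, with 4 at an unadjusted p under 0.05 (camera adjusted p = 0.0442, and 0.270 with an estimated correlation), with GLT1 at 13.6 ± 1.9 against 1.54 ± 0.933 RPM. Camera called nuclear photosynthesis genes down (adjusted p = 2.61e-08, and 0.121 with an estimated correlation) and chloroplast-encoded genes down (adjusted p = 4.67e-05, and 0.28 with an estimated correlation). No member of either passed, with 6 and 0 at an unadjusted p under 0.05 in limma.

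Loss of DCL2 in the dcl4-2 background lowered 22-nt RNAs at the nitrate reductases, at SMXL4 and at GLT1 on MS. NIA1 was lower in dcl4-2 dcl2-1 than in dcl4-2 by a log2 fold change of -5.67 ± 0.37 and NIA2 by -5.40 ± 0.44 (SE, limma adjusted p = 3.62e-24 and 3.00e-18). SMXL4 had no reads in any of the 3 dcl4-2 dcl2-1 libraries, against 18 ± 1.46 RPM in dcl4-2 (limma adjusted p = 2.79e-04). GLT1 was at 0.336 ± 0.583 against 14.3 ± 3.05 RPM, a log2 fold change of -3.58 ± 0.80 (SE, limma adjusted p = 0.00681). The pseudogene AT5G32511 was at 0.304 ± 0.527 against 40.9 ± 2.23 RPM, a log2 fold change of -5.08 ± 0.83 (SE, limma adjusted p = 2.79e-05). MIR156a was higher in dcl4-2 dcl2-1, at 237 ± 26.2 against 24.5 ± 6.05 RPM, a log2 fold change of 3.24 ± 0.67 (SE, limma adjusted p = 0.00213), and AT4G20830 and AT1G13470 were at 6.88 ± 5.13 and 7.94 ± 11.3 RPM against no reads. For each of these genes the libraries did not overlap. SMXL5, at 0.304 ± 0.527 against 10.5 ± 6.55 RPM, did not pass (limma adjusted p = 0.0725).

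By limma, 4 genes were higher and 33 lower on MS, 16 of the latter pseudogenes, and 464 had an unadjusted p under 0.05, while the libraries did not overlap in 3 and 32 of them. The compared groups alone gave 0 higher and 6 lower, and the MIRNA rescaling, which shifted the all-gene median of -0.11 by -0.13, 2 and 63. Leaving out dcl4-2 dcl2-1 MS library C, the shallowest library, gave 2 higher and 20 lower genes. AT1G13470 lost its call without that library or any dcl4-2 MS library (limma adjusted p from 0.0884 to 0.606), and AT4G20830 without any but dcl4-2 dcl2-1 MS library B (0.0754 to 0.239). With the most unequal solution MIR156a and MIR319c lost their calls (0.932 and 0.533). AT3G18280, named after its values were seen, was the other higher gene, with overlapping libraries. In the MIRNA list, MIR156a rose and MIR319c, whose libraries overlapped, fell, with 2 higher and 1 lower adjusted over the list alone (camera up, adjusted p = 1.18e-04, and 0.396 with an estimated correlation). The MIR319c call ended without dcl4-2 MS library A or C or dcl4-2 dcl2-1 MS library C (0.0726 to 0.510). SMXL4 was the 1 SMXL member that fell, with 2 adjusted over the list alone (camera down, adjusted p = 0.00644, and 0.170 with an estimated correlation). None of the PPR targets (camera adjusted p = 0.523) or other miRNA and tasiRNA targets (0.423) passed, with 0 and 2 at an unadjusted p under 0.05 in limma. Camera called nuclear photosynthesis genes up (adjusted p = 0.0233, 0.514 with an estimated correlation and 0.369 with the MIRNA rescaling). No member passed, with 1 at an unadjusted p under 0.05 in limma. The chloroplast feature ATCG00650 fell, at 1.52 ± 2.64 against 16.6 ± 5.63 RPM, a call that ended without dcl4-2 MS library A or C or dcl4-2 dcl2-1 MS library B or C (0.0709 to 0.118).

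On ABA, 22-nt RNAs at SMXL4, AT2G03500, AT5G43740, ADC2 and 249 pseudogenes were lower in dcl4-2 dcl2-1 than in dcl4-2. SMXL4 was at 0.302 ± 0.523 against 82.5 ± 56.5 RPM (SD, n = 3 each), a log2 fold change of -5.80 ± 0.79 (SE, limma adjusted p = 9.82e-08). AT2G03500 had no reads against 35.1 ± 15.1 RPM (limma adjusted p = 6.23e-10). AT5G43740 was at 0.302 ± 0.523 against 43.2 ± 16.8 RPM, a log2 fold change of -5.09 ± 0.81 (SE, limma adjusted p = 9.72e-06), and ADC2 at 1.13 ± 0.983 against 125 ± 172 RPM, a log2 fold change of -4.97 ± 0.82 (SE, limma adjusted p = 2.28e-05). The pseudogene AT5G32197 was at 0.261 ± 0.451 against 71.1 ± 96.2 RPM. In the authors' deposited table NIA1 and NIA2 had log2 fold changes of -8.22 and -8.26, with adjusted p of 4.09e-41 and 3.59e-33 from the authors' test. The higher genes with separate libraries were AT3G15450 at 4.61 ± 0.953 against 0.0789 RPM, LIN2, FRO2, AT5G47300 and STN7. SMXL5 at 3.31 ± 2.39 against 20.9 ± 11.7 RPM, MIR173 at 6.98 ± 3.77 against 29.3 ± 5.28 RPM and MIR168a at 62.9 ± 46.1 against 76.8 ± 20.9 RPM did not pass (limma adjusted p = 0.0773, 0.103 and 0.743).

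By limma, 6 genes were higher and 352 lower on ABA, 249 of the latter pseudogenes, and 1341 had an unadjusted p under 0.05, while the libraries did not overlap in 5 and 352 of them. The all-gene median log2 fold change was -0.51, and the MIRNA rescaling shifted it by 0.35 and left 1 higher and 6 lower genes. The compared groups alone gave 0 and 9, voom weights 107 and 197, and the authors' deposited table gave 15 higher and 165 lower, of which limma shared 2 and 129. Leaving out dcl4-2 ABA library C gave 0 higher and 73 lower, dcl4-2 ABA library A 0 and 94, and dcl4-2 dcl2-1 ABA libraries A, B and C 10 and 220, 8 and 161, and 4 and 122. AT3G15450, LIN2, FRO2, AT5G47300 and STN7 lost their calls without dcl4-2 ABA library A, B or C or dcl4-2 dcl2-1 ABA library C (limma adjusted p from 0.0585 to 0.275). AT3G15450, FRO2 and AT5G47300 lost them also without dcl4-2 dcl2-1 ABA library B (0.0774 to 0.0858), and AT3G15450 and AT5G47300 without A (0.0851 and 0.0613).

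Of the MIRNA loci 10 fell on ABA, and 11 adjusted over the list alone, with MIR166f and MIR166e at 395 ± 132 and 396 ± 131 against 1542 ± 580 and 1543 ± 579 RPM. Camera called them down (adjusted p = 0.0172, and 0.567 with an estimated correlation). Of 17 PPR targets 6 fell, and 10 adjusted over the list alone (camera down, adjusted p = 8.68e-05, and 0.180 with an estimated correlation). AT1G62860 and AT1G63130 among them had no reads against 6.01 ± 3.39 and 8.49 ± 6.12 RPM, and lost their limma calls without dcl4-2 ABA library C (adjusted p = 0.0575 and 0.102). Of 13 other miRNA and tasiRNA targets 6 fell, and 8 adjusted over the list alone, with sums of 2.03 against 92.2 ± 30.4 RPM (camera down, adjusted p = 5.34e-06, and 0.0191 with an estimated correlation). AT5G43730 was at 0.302 ± 0.523 against 19 ± 5.91 RPM. Of the silencing machinery AGO1 and AGO2 fell, with no reads against 3.50 ± 1.35 and 4.73 ± 2.61 RPM (limma adjusted p = 0.0315 and 0.0271). The AGO1 call ended without any 1 of the 6 libraries, at limma adjusted p from 0.0609 to 0.109, and the AGO2 call without any but dcl4-2 ABA library B (0.062 to 0.180). In nitrogen uptake and assimilation 3 fell, the nitrate transporter gene NRT1.1, named after its values were seen, GLT1 at 1.77 ± 2.42 against 13.6 ± 1.9 RPM and the nitrite reductase gene NIR1 at 1.3 ± 2.26 against 8.58 ± 2.57 RPM, while camera called no direction (adjusted p = 0.901). GLT1 lost its call without any but dcl4-2 dcl2-1 ABA library B (0.057 to 0.135) and NIR1 without any but dcl4-2 dcl2-1 ABA library A (0.0787 to 0.139). SMXL4 was the 1 SMXL member that fell (camera adjusted p = 0.0477, and 0.314 with an estimated correlation). Camera called nuclear photosynthesis genes up (adjusted p = 1.15e-10, and 0.0688 with an estimated correlation). It called chloroplast-encoded genes up (2.12e-08, 0.132 with an estimated correlation and 0.706 by fry), but ATCG00640 and ATCG00650 fell by limma. The first call ended without dcl4-2 ABA library C (0.0575), the other without any but dcl4-2 dcl2-1 ABA library A (0.0570 to 0.224). Of the mitochondrion-encoded genes, ATMG00513 fell (limma adjusted p = 0.0477), a call that ended without any but dcl4-2 dcl2-1 ABA library B (0.0648 to 0.2).

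On MS, 4 of the 5 genes higher in dcl4-2 than in Col-0 were lower in dcl4-2 dcl2-1 than in dcl4-2 (NIA1, NIA2, FD1 and SAC9). On ABA it was 7 of 8 with NIA1 and NIA2 untested (SMXL4, AT2G03500, ADC2, BGLU29, NAC083, ABCC3 and AT3G16560). Of the 300 genes raised by ABA in dcl4-2, 149 were lower in dcl4-2 dcl2-1 on ABA. These pairs of comparisons share the dcl4-2 libraries, so the lists are not independent and no chance level is given. The overlap of 149 fell to 7 without dcl4-2 ABA library C, 31 without library A and 2 with the MIRNA rescaling. The overlap of 4 fell to 2 without any Col-0 MS library, dcl4-2 MS library B or dcl4-2 dcl2-1 MS library A or C. With the compared groups alone the overlaps of 4, 7 and 149 became 0, 3 and 2. The overlap of 7 fell to 3 without Col-0 ABA library A and 2 with the MIRNA rescaling.

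Against Col-0 on MS, dcl4-2 dcl2-1 had lower 22-nt RNAs at 70 genes, among them REV, PHB, HB-8, SMXL4, SMXL5 and GLT1. REV, PHB, SMXL4 and HB-8 had no reads in any of the 3 dcl4-2 dcl2-1 libraries, against 97.9 ± 80.7, 65.9 ± 46.2, 54.3 ± 29.6 and 41.8 ± 31.9 RPM in Col-0 (SD, n = 3 each; limma adjusted p = 4.55e-09, 3.07e-08, 1.70e-07 and 4.55e-09). GLT1 was at 0.336 ± 0.583 against 62.2 ± 43.6 RPM, a log2 fold change of -5.37 ± 0.80 (SE, limma adjusted p = 9.34e-07). SMXL5 was at 0.304 ± 0.527 against 84.0 ± 67.8 RPM, a log2 fold change of -5.24 ± 0.86 (SE, limma adjusted p = 1.39e-05). The PPR genes AT1G63080 and AT1G62914 had no reads against 24.2 ± 13.0 and 22.9 ± 9.88 RPM, and the pseudogenes AT3G43862 and AT5G32511 were at 0.336 ± 0.583 and 0.304 ± 0.527 against 58.7 ± 45.8 and 36.3 ± 25.3 RPM. MIR319c was at 26.4 ± 15 against 350 ± 171 RPM, a log2 fold change of -3.74 ± 0.41 (SE, limma adjusted p = 3.30e-11). MIR156a was the 1 higher gene, at 237 ± 26.2 against 37.5 ± 22.9 RPM (limma adjusted p = 0.00688). For each gene named so far the libraries did not overlap. NIA1 had a log2 fold change of -1.69 ± 0.37 and NIA2 of -1.80 ± 0.44 (SE, limma adjusted p = 0.00324 and 0.0116), with overlapping libraries for NIA2. With the most unequal solution MIR156a, NIA1 and NIA2 lost their calls (limma adjusted p = 0.860, 0.0903 and 0.0739). Without Col-0 MS library C the limma adjusted p was 0.212 for NIA1, 0.337 for NIA2 and 0.175 for MIR156a, and NIA2 lost its call also without Col-0 MS library A (0.0855) or dcl4-2 dcl2-1 MS library A (0.225).

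By limma, 1 gene was higher and 70 lower on MS, 20 of the latter pseudogenes, and 698 had an unadjusted p under 0.05, while the libraries did not overlap in 1 and 64 of them. With the compared groups alone 0 genes passed, with 371 at an unadjusted p under 0.05. Leaving out Col-0 MS library C gave 0 higher and 37 lower, and dcl4-2 dcl2-1 MS library C 3 and 38. Of 17 PPR targets AT1G62914, AT1G63080, AT1G63400 and, named after their values were seen, RPF3 and AT1G63130 fell, and 10 adjusted over the list alone (camera down, adjusted p = 6.11e-10, and 0.0445 with an estimated correlation). Of 5 SMXL members SMXL3, SMXL4 and SMXL5 fell, both adjustments alike (camera down, adjusted p = 1.20e-06, and 0.0227 with an estimated correlation). Of 13 other miRNA and tasiRNA targets 3 fell, PAP1, named after its values were seen, AGO2, with no reads against 17.6 ± 13.2 RPM, and AT5G43740 at 0.641 against 28.2 ± 18.5 RPM (camera adjusted p = 0.258). In the MIRNA list MIR156a rose and MIR319c fell, with 5 and 3 adjusted over the list alone. Camera called it up (adjusted p = 3.88e-04, 0.428 with an estimated correlation and 0.763 by fry). In nitrogen uptake and assimilation GLT1 fell. Of 83 chloroplast-encoded genes 3 fell, with 2 higher and 10 lower adjusted over the list alone, among them ATCG00650 and ATCG00080. These 2 lost their limma calls without Col-0 MS library C (adjusted p = 0.0533 and 0.0692), ATCG00650 also without dcl4-2 dcl2-1 MS library B (0.0633) and ATCG00080 without C (0.0804).

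On ABA, 11 of the 35 genes lower in dcl4-2 dcl2-1 than in Col-0 were listed PPR targets, which may share reads, and 13 were pseudogenes. The PPR genes AT1G63400, AT1G62914 and AT1G63080 were at 0.261 ± 0.451, 0.261 ± 0.451 and 1.3 ± 2.26 against 146 ± 90.5, 144 ± 85.9 and 151 ± 87.4 RPM (SD, n = 3 each). Their log2 fold changes were -6.75 ± 0.77, -6.75 ± 0.78 and -6.33 ± 0.81 (SE, limma adjusted p = 8.84e-11, 1.71e-10 and 5.15e-09). AT1G62910, AT1G63130, RPF3, AT1G63150 and AT1G63070 had no reads against 29.9 ± 7.55, 29.1 ± 7.17, 27.8 ± 7.63, 20.8 ± 6.86 and 10.1 ± 3.44 RPM. AT3G06435 was at 122 ± 21.1 against 1441 ± 94.2 RPM, a log2 fold change of -3.56 ± 0.38 (SE, limma adjusted p = 1.27e-11), and AT3G44580 at 5.50 ± 5.13 against 58.9 ± 21.8 RPM. NIA1 was higher by 2.92 ± 0.37 and NIA2 by 2.80 ± 0.44 on the log2 scale (SE, limma adjusted p = 5.15e-09 and 4.01e-06). For each of these genes the libraries did not overlap. AT3G44580 lost its call without Col-0 ABA library C or dcl4-2 dcl2-1 ABA library C (limma adjusted p = 0.106 and 0.147).

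By limma, 2 genes were higher and 35 lower on ABA, 13 of the latter pseudogenes, and 1031 had an unadjusted p under 0.05, while the libraries did not overlap in 2 and 35 of them. The all-gene median was -0.44, and the MIRNA rescaling shifted it by 0.22 and gave 2 higher and 9 lower, and the compared groups alone 0 and 7. Leaving out Col-0 ABA libraries A, B and C gave 2 and 14, 2 and 19, and 2 and 10, and dcl4-2 dcl2-1 ABA libraries B and C 4 and 19, and 3 and 14. Of 17 PPR targets 11 fell, and 17 adjusted over the list alone (camera down, adjusted p = 2.07e-33, and 0.00161 with an estimated correlation), with sums of 1.82 ± 3.16 against 594 ± 311 RPM. Against the other genes, whose median fell, camera called ABA-responsive genes up (adjusted p = 0.0457, 0.233 with an estimated correlation and 0.0719 with the MIRNA rescaling), as it did nuclear photosynthesis genes (0.0366, and 0.544 with an estimated correlation) and chloroplast-encoded genes (0.0172, and 0.514 with an estimated correlation). Their own median log2 fold changes were 0.02, -0.06 and -0.17, and fry called none of the 3 (adjusted p from 0.560 to 0.925). The chloroplast feature ATCG00640 fell, with no reads against 6.55 ± 3.82 RPM, a call that ended without any 1 of the 6 libraries, at limma adjusted p from 0.0599 to 0.219. MIRNA loci (camera adjusted p = 0.823), SMXL members (0.466) and other miRNA and tasiRNA targets (0.311) had 0 members past limma's threshold, with 4, 0 and 4 at an unadjusted p under 0.05.

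Of 8 ABA-responsive genes with enough reads, 0 passed limma's threshold in any of the 9 comparisons, with at most 1 at an unadjusted p under 0.05. Seed storage genes were not tested. Camera called no direction for the silencing machinery or the mitochondrion-encoded genes in any comparison.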

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

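The splits of the samples, both rescalings used as tests, the test without dcl4-2 ABA library C, and the contrast of ABA effects between dcl4-2 dcl2-1 and Col-0 were chosen after the results were seen.

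Genes drew attention where limma's test found the ABA effect to differ between genotypes. Between dcl4-2 and Col-0 the effects differed on the log2 scale by 7.32 for SMXL4, 5.53 for PHB, 5.22 for SMXL5, 5.20 for HB-8, 5.09 for AT2G03500 and 5.06 for AT5G17980. AT5G17980 stood at 14.2 RPM in Col-0 on MS and 3.53 RPM in dcl4-2 on ABA and had no reads in the other groups. Where a group had at most 1 read, as for SMXL4, AT5G17980, AT2G03500, HB-8 and PHB, the size depends on the pseudocount. Between dcl4-2 dcl2-1 and dcl4-2 they differed by 2.68 for MIR399a, -5.37 for MIR156a, -5.09 for AT2G03500, -2.76 for MIR166f and MIR166e, and -2.75 for MIR166g, of which AT2G03500 alone kept its call with the most unequal solution. Of 50 splits of the libraries by medium within genotype, 5 called as many genes as the first contrast and 3 as many as the second, the real split included, so chance is not excluded for either count. The real counts were 15 and 12 and the highest of the other splits 141 and 133. A split that swaps the media of libraries in 1 genotype turns a shared ABA effect into a difference, so high counts can follow from how the splits are built.

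Between dcl4-2 dcl2-1 and Col-0 the ABA effect differed by 4.61 for both NIA1 and NIA2 (SE 0.53 and 0.62, limma adjusted p = 2.78e-10 and 1.16e-07), which fell in Col-0 and rose in dcl4-2 dcl2-1, the rise not passing with the most unequal solution (0.15 for both), where the difference did. The smallest difference under median-of-ratios and MIRNA rescaling was 4.72, which argues against the library scale as the cause. Leaving out any 1 of the 12 libraries gave a limma adjusted p of at most 1.59e-04, which argues against a single library, and the largest over the other settings that gave a value was 0.0198, for NIA2 with no filter. Voom weights gave none, as these genes were left out. The sharing of reads between these paralogs was not tested. An effect of genotype stays a hypothesis, found and tested on the same data.

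ABA in dcl4-2 gave 300 higher and 14 lower genes. Thinning dcl4-2 ABA libraries A and B to MS depth left 172 higher genes, 144 of the 300, and 18 lower. The 300 had a median log2 fold change of 2.18 (SE 0.71) against 2.31 (0.66). More stayed higher than lower, but the 300 were chosen at full depth, so depth may contribute. Array weights gave 642 and 54. Voom weights, which also change the log scale and leave out NIA1 and NIA2, gave 112 and 148, and why was not tested. Library scale may contribute, since MIRNA rescaling left 6 higher genes and a median of 1.4 (gene SE 0.71), the smaller folds ending the calls. But MIRNA loci rose by limma, so scale and biology cannot be told apart. Without dcl4-2 ABA library C, where 233 of the 300 genes were highest against 42.5% of all tested genes, 15 were higher. The median was 2.05 (gene SE 0.72), so calls ended with a smaller fold and larger error. Whether library C carries a response of its own stays open.

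For each of the 9 comparisons between groups, 1 of 10 splits of the libraries, the real one, called as many genes, and 10 splits are too few for a share under 0.05. The real count and the highest other were 40 and 2 for ABA in Col-0, 314 and 4 in dcl4-2, and 13 and 0 in dcl4-2 dcl2-1. They were 26 and 3 for dcl4-2 against Col-0 on MS and 13 and 0 on ABA, 37 and 1 for dcl4-2 dcl2-1 against dcl4-2 on MS and 358 and 0 on ABA, and 71 and 2 for dcl4-2 dcl2-1 against Col-0 on MS and 37 and 0 on ABA.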

How the results depend on the processing

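Voom weights, the authors' calls, thinning, the most unequal solution, leaving out the 2 libraries under 0.2 M reads and totals without NIA1 and NIA2 were chosen after the results were seen. The 9 counts given per setting follow the order ABA in Col-0, in dcl4-2 and in dcl4-2 dcl2-1, dcl4-2 against Col-0 on MS and ABA, dcl4-2 dcl2-1 against dcl4-2 on MS and ABA, and dcl4-2 dcl2-1 against Col-0 on MS and ABA, where limma gave 40, 314, 13, 26, 13, 37, 358, 71 and 37 in the report. The differences between ABA effects were 15 for dcl4-2 against Col-0 and 12 for dcl4-2 dcl2-1 against dcl4-2. The 6 overlaps follow the order higher in dcl4-2 and lower in dcl4-2 dcl2-1 on MS (4) and ABA (7), raised by ABA in dcl4-2 and lower in dcl4-2 dcl2-1 (149), and the same ABA direction in Col-0 and dcl4-2 (12), Col-0 and dcl4-2 dcl2-1 (8), and dcl4-2 and dcl4-2 dcl2-1 (8). Median-of-ratios rescaling and a minimum absolute log2 fold change of 1 moved no count by over 1.5 times. The cause was not tested for the shifts below, except that no filter raises the number of tests, and fewer libraries leave fewer degrees of freedom.

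A pseudocount of 0.1 gave 12, 37, 14, 6, 3, 25, 80, 42 and 13 genes, differences of 5 and 7, and overlaps of 2, 2, 13, 4, 3 and 7. No filter gave 13, 43, 7, 5, 7, 7, 73, 19 and 20, differences of 3 and 3, and overlaps of 2, 4, 18, 3, 1 and 5. Use of the compared groups alone gave 0, 7, 0, 0, 15, 6, 9, 0 and 7 by limma, differences of 19 and 2, and overlaps of 0, 3, 2, 0, 0 and 0, while 926, 148, 177 and 371 genes had an unadjusted p under 0.05 in the 4 comparisons at 0. The MIRNA rescaling gave 27, 24, 7, 46, 5, 65, 7, 106 and 11, differences of 3 and 4, and overlaps of 7, 2, 2, 3, 2 and 3. Array weights gave 49, 696, 18, 9, 229, 33, 961, 64 and 219, differences of 27 and 29, and overlaps of 2, 132, 382, 17, 8 and 9. Voom weights, fitted without NIA1 and NIA2, gave 38, 260, 8, 12, 125, 22, 304, 35 and 22, differences of 21 and 16, and overlaps of 0, 52, 64, 12, 7 and 6.

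A pseudocount of 5 moved dcl4-2 against Col-0 on ABA to 29, dcl4-2 dcl2-1 against dcl4-2 on MS to 20, and the second and last overlaps to 21 and 5. A filter of 5 RPM in 3 libraries moved ABA in dcl4-2 dcl2-1 to 24, dcl4-2 dcl2-1 against Col-0 on ABA to 112, the first overlap to 2 and the overlap of 12 to 21. Thinning moved ABA in dcl4-2 to 190, dcl4-2 dcl2-1 against dcl4-2 on ABA to 215 and the overlap of 149 to 78. The most unequal solution moved ABA in dcl4-2 dcl2-1 to 5, the difference between dcl4-2 dcl2-1 and dcl4-2 to 3, and the last overlaps to 3 and 5. Without the 2 libraries under 0.2 M reads, dcl4-2 dcl2-1 against dcl4-2 on ABA gave 212, and the first overlaps were 2 and 11. The authors' deposited table gave 132 genes for ABA in dcl4-2, 5 in dcl4-2 dcl2-1 and 180 for dcl4-2 dcl2-1 against dcl4-2 on ABA.

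Ratios of summed levels under the MIRNA rescaling were 0.591 for ABA in Col-0, which turned its direction, and 1.07 in dcl4-2 dcl2-1. For dcl4-2 dcl2-1 they were 0.352 against dcl4-2 on MS and 0.515 and 0.934 against Col-0 on MS and ABA. Without the 10 highest features the ratio was 1.96 for ABA in dcl4-2, 0.820 and 1.22 for dcl4-2 against Col-0 on MS and ABA, and 0.828 and 0.505 for dcl4-2 dcl2-1 against dcl4-2. Without NIA1 and NIA2 these were 2.15, 0.846, 1.23, 0.835 and 0.491. Without MIRNA, chloroplast and mitochondrial loci the last 4 were 1.63, 17.4, 0.321 and 0.0324, and dcl4-2 dcl2-1 against Col-0 on MS was 0.525.

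Leaving out 1 library at a time, the lowest and highest counts were 10 and 47 for ABA in Col-0 (without MS library C and B), 16 and 273 in dcl4-2 (ABA library C and B), and 9 and 37 in dcl4-2 dcl2-1 (ABA library B and MS library B). For dcl4-2 against Col-0 they were 8 and 34 on MS (Col-0 library C and B) and 6 and 11 on ABA (Col-0 library A, dcl4-2 library A). For dcl4-2 dcl2-1 against dcl4-2 they were 22 and 38 on MS (dcl4-2 dcl2-1 library C and A) and 73 and 304 on ABA (dcl4-2 library C and B). For dcl4-2 dcl2-1 against Col-0 they were 37 and 93 on MS (Col-0 library C and B) and 12 and 35 on ABA (Col-0 library C, dcl4-2 dcl2-1 library A). The differences ranged from 5 to 23 (Col-0 MS library A and B) and 4 to 19 (dcl4-2 ABA library C, dcl4-2 dcl2-1 MS library C), and the overlaps from 2 to 5, 3 to 8, 7 to 141, 2 to 10, 1 to 8 and 4 to 9. The ratios of summed levels, in the order of the 9 counts, ranged from 1.26 to 1.53, 9.84 to 12.6, 1.24 to 1.36, 1.28 to 1.63, 10.5 to 12.8, 0.419 to 0.534, 0.0527 to 0.0575, 0.645 to 0.721 and 0.587 to 0.714.

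For the named genes no setting reversed a call. Calls were lost in 139 of 411 values with the compared groups alone, 92 with no filter, 73 with the MIRNA rescaling, 70 with a pseudocount of 0.1, 18 with a pseudocount of 5, 12 with array weights and 1 with median-of-ratios rescaling, and in 311 of 2640 values when 1 library was left out. Calls were gained in 20 values with array weights, 16 with the filter of 5 RPM and at most 21 elsewhere. Of 37 camera calls among 90 list tests, 29 were lost with an estimated correlation and 17 with fry, which gained 6. No paired analysis was possible because the deposited columns are group means and the recovered libraries carry no replicate number. Voom weights on recovered reads were used in place of the count tests of edgeR and DESeq2, which were not run. Depth limits most what can be said of genes under a few RPM in dcl4-2 dcl2-1 MS library C, where 1 read was worth 10.5 RPM.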

Other observations

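The pseudogene class and its tests were chosen after the results were seen.

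Annotated pseudogenes, not told apart from transposon genes, were 40.6% of the genes tested. Among the 300 genes higher on ABA in dcl4-2 they were 210, or 70.0% (Fisher's exact test, Benjamini-Hochberg adjusted p = 6.51e-25 over 18 tests), and among the 352 genes lower in dcl4-2 dcl2-1 than in dcl4-2 on ABA they were 249, or 70.7% (adjusted p = 1.47e-30). In Col-0 they were 6 of 18 genes higher on ABA (adjusted p = 0.714) and 0 of 22 lower (adjusted p = 6.83e-05). On MS, 1 of 21 genes lower in dcl4-2 than in Col-0 was a pseudogene (adjusted p = 0.00205), as were 1 of 14 genes lower on ABA in dcl4-2 (0.0347) and 0 of 10 higher on ABA in dcl4-2 dcl2-1 (0.0263). The share did not differ by this test among the genes lower in dcl4-2 dcl2-1 than in dcl4-2 on MS (16 of 33, adjusted p = 0.486) or than in Col-0 on MS (20 of 70, 0.111) and ABA (13 of 35, 0.776). The remaining tests, on lists of 8 genes or fewer, did not pass (adjusted p of at least 0.0637). Genes are not independent replicates and repeats can share reads, so these p-values describe the lists. The list of 300 falls to 15 without dcl4-2 ABA library C.

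The contrast of ABA effects between dcl4-2 dcl2-1 and Col-0, added after the data were seen, gave 10 genes with the more positive and 1 with the more negative log2 change in dcl4-2 dcl2-1 by limma, and 427 had an unadjusted p under 0.05. Beside NIA1 and NIA2 the class III HD-ZIP genes HB-8, PHB and REV differed, by 5.35, 5.67 and 5.69 on the log2 scale (limma adjusted p = 6.35e-05, 7.62e-04 and 7.62e-04), as did SMXL4 and SMXL5, by 5.76 and 5.93 (0.00111 and 0.00288). These 5 genes fell on ABA in Col-0 and stood at no more than 3.31 RPM on either medium in dcl4-2 dcl2-1, so their differences depend on the pseudocount. MIR156a differed by -4.35 (limma adjusted p = 0.00805, and 0.728 with the most unequal solution).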
